A study of Mus musculus with 13 samples.

How the data were processed

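The deposited UMI counts per barcode and gene came from single-cell 10x Genomics v2 libraries of the mouse ventral prostate, 13 in all. Per the labels they were made with kallisto, bustools and Cell Ranger, for which no versions are stated. The submitters' processing notes name the build hg19, which cannot be right for these matrices because the gene identifiers are mouse Ensembl identifiers. Groups were taken from the labels alone: intact wild type (n = 3), castrated wild type (n = 3), intact PTEN (n = 2), castrated PTEN (n = 3) and castrated PTEN with 4EBP1 (n = 2). The labels give separate samples and do not state which animals they came from. Coordinates and symbols follow GENCODE vM21.

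Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs. That gave 5496, 3183 and 5319 barcodes in the intact wild type, 6159, 1265 and 7090 in the castrated wild type, 4864 and 6926 in intact PTEN, 5080, 5386 and 7828 in castrated PTEN and 4982 and 4838 in the 4EBP1 libraries. Wild-type castrated replicate 2 had the lowest depth, 3258032 UMIs. Doublet scores came from scrublet in scanpy 1.11.5. Its automatic threshold called 2 to 13 barcodes in most libraries, so the top 0.8% per 1000 barcodes were removed, 3154 barcodes in all. Counts were clustered with 2500 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.5 (leidenalg 0.10.2, Python 3.11.15). The 40 clusters were named by marker genes, of which 5 stayed unnamed.

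UMIs were summed per library and class and analysed with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr, robust quasi-likelihood fits of all 13 libraries with 1 coefficient per group, and adjusted p by Benjamini and Hochberg at 0.05. Classes needed at least 20 cells in a library. The difference between both castration responses was tested as an interaction in luminal cells. Cell numbers of 13 classes were tested with edgeR as well. Of 39 gene lists fixed in advance, those with at least 3 members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one. A list can pass camera without any of its genes passing. All standard errors and intervals cover the counts and the spread between libraries given. They do not cover differences between animals that were not sampled.

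Genes were named by a rule: adjusted p under 0.05, an official symbol, a group mean of at least 20 CPM, every library of 1 group above every library of the other, and under 10% estimated free RNA. The 10 largest changes per direction were taken in luminal cells and 5 in other classes, with up to 4 members per list as examples. Pten, Eif4ebp1 and Ar were taken in every comparison. For a gene without UMIs in 1 group the fold is a lower bound against a floor of 3 counts over that group. Free RNA was estimated from barcodes with 1 to 50 UMIs, scaled by markers of macrophages, neutrophils and fibroblasts in luminal cells and by secretory products in other classes. A second estimate was scaled by markers of intermediate luminal cells. Cluster 26, which held most basal cells of PTEN mice, had 6 of these markers raised. If basal cells make that RNA, the second estimate is too high for them.

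Alternatives were: RLE factors, total UMIs, no count filter, DESeq2 1.42.0, at least 1000 UMIs, at most 10% mitochondrial UMIs, doublets kept, the replicate number as a block, the compared groups alone, genes under 10% free RNA by either estimate, single clusters left out, and each library left out in turn. After leaving out a library of a pair, the remaining library is taken to vary as the other groups do. The pipeline was tested on simulated data with 200 changed genes: 4-fold changes were found in 80% of luminal and 32% of fibroblast genes at best and worst, and 2-fold changes in 1% to 10%, with 0 to 5 false calls. The simulation gave every gene a dispersion of 0.1, and at that spread 2-fold changes were mostly missed. Real genes that vary less can pass at smaller changes, as Cd63 did in macrophages of castrated wild-type mice (0.67, SE 0.18). Cell numbers were simulated at the same dispersion with 3 classes changed 4-fold in intact PTEN libraries. The test found 96.7% of these changes, with 0.35 false calls per draw over 20 draws. Other cell classes were counted and not compared gene by gene here. Velocity, trajectories and reads were not analysed here.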

Results

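RNA of single cells from the ventral lobe of the mouse prostate was counted as unique molecular identifiers (UMIs) with the 10x Genomics v2 kit in 13 libraries. The labels gave 5 groups: intact wild-type mice (3 libraries), castrated wild-type mice (3), intact mice with PTEN as their CRISPR status (2), castrated PTEN mice (3) and castrated PTEN mice with 4EBP1 (2). Pten encodes a phosphatase that limits signalling from PI3 kinase. The gene product 4EBP1 binds the cap-binding factor eIF4E and limits translation. Per the labels the PTEN mice were castrated at about 4 months, the 4EBP1 mice were also given doxycycline from about that age, and mice were euthanized at about 6 months. Castration age was not stated for wild-type mice. The deposited libraries held 31721167, 15662180 and 11602632 UMIs in the intact wild type, 14506740, 3258032 and 19043456 in the castrated wild type, 16036121 and 31690946 in intact PTEN, 15953302, 17133400 and 36372230 in castrated PTEN, and 11886480 and 20473913 in the 4EBP1 libraries. After filters and removal of 3154 likely doublets, 65262 cells were analysed, of which 25366 were luminal, 11578 basal, 4760 macrophages and 7656 fibroblasts.

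Expression is given as CPM, UMI counts scaled with TMM factors (mean ± SD over libraries) and differences as log2 fold changes with their standard error (SE). Genes named for the size of their change separated the groups: each library of 1 group lay above each library of the other. List members, Pten, Eif4ebp1 and Ar were named without that condition. In luminal cells of the intact wild type, the secreted protease inhibitor Spink1 had 498357 ± 255439 CPM (n = 3). This is not its share of UMIs, as the TMM factors of these libraries were 0.505, 0.553 and 0.723. Spink1 made up 30.2, 27.4 and 7.96% of all UMIs in replicates 1, 2 and 3. Scaled by total UMIs without TMM factors, the median of all luminal genes therefore moved by 0.93 for intact PTEN against intact wild type, by 1.04 for castrated against intact wild type, by 0.13 for castrated against intact PTEN and by -0.91 for the difference between both castration responses. Directions below are relative to that median.

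Luminal cells of intact PTEN mice, compared with those of intact wild-type mice (n = 2 and 3) to ask what goes with PTEN status before castration, held more RNA of interferon-response genes and less RNA of 6 of 9 ventral secretory products. Wfdc18, a secreted protease inhibitor of the WAP family, rose from 9.94 ± 7.64 to 5845 ± 985 CPM (log2 fold change 9.28, SE 0.88, edgeR adjusted p = 6.67e-05). The antibacterial lectin Reg3g rose from 2.67 ± 2.07 to 1358 ± 299 CPM (9.25, SE 0.79, edgeR adjusted p = 2.92e-05). Cdkn2a, which encodes the cell-cycle inhibitors p16 and p19ARF, rose from 0.185 ± 0.181 to 80.4 ± 18.1 CPM (8.48, SE 0.38, edgeR adjusted p = 1.65e-09). Defb50, a defensin of ventral luminal cells, fell from 69179 ± 2909 to 1639 ± 23.1 CPM (-5.40, SE 0.26, edgeR adjusted p = 4.48e-09). Olfm4, a glycoprotein of intestinal stem cells and neutrophils, had 267 ± 81.7 CPM against no UMI in the wild type, at least 1561-fold higher.

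The remaining genes of largest rise were the antibacterial Reg3b (10.90), the iron-binding Ltf (10.04), the interferon-induced DNA sensor Ifi202b (9.77), the ubiquitin-like Ubd (9.01), the neuropeptide gene Calcb (8.69) and the neutrophil chemokine Cxcl5 (8.43). Among the secretions, Pbsn fell by 9.41, Msmb fell by 7.36, the defensin Defb10 fell by 8.41, the androgen-binding-protein gene Scgb1b20 fell by 6.50, Spink8 fell by 6.30 and the mucin-like Smgc fell by 5.27. Ms4a5 fell by 10.50, the calmodulin regulator Pcp4 fell by 7.11 and the metallothionein Mt3 fell by 5.96. Ms4a5 was spread widely in the wild type (309 ± 467 CPM).

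All 20 interferon-response genes rose (median 4.18; camera adjusted p = 1.87e-56, 0.000135 with an estimated correlation), among them Isg15 (5.76), Oasl2 (4.72), Irf7 (4.68) and Usp18 (4.59). All 13 genes of MHC class I presentation rose (median 1.82), such as the peptide transporter Tap1 (2.66), H2-Q4 (2.46) and the immunoproteasome subunit Psmb8 (2.38). Of 21 inflammatory chemokine and NF-kB genes, 17 rose, with Cxcl2 (5.04), Tnf (4.55) and Tnfaip3 (2.09) among them. Rises were found for 19 of 22 cell-cycle genes, such as Mcm3 (2.70), Ccna2 (2.68) and Mki67 (2.50), for 14 of 15 glycolysis genes, such as the lactate exporter Slc16a3 (4.02), Hk1 (1.79) and Pgk1 (1.60), and for 13 of 15 p53 and senescence genes, such as Cdkn2b (3.24) and Phlda3 (3.16). All 14 genes of the unfolded protein response, chaperones of the endoplasmic reticulum, fell (median -1.78): Sdf2l1 fell by 2.87, Creld2 fell by 2.60, Pdia6 fell by 2.46 and Edem1 fell by 1.40. Counts adjusted over the list alone were the same for these 7 lists. With camera's preset correlation every one passed, and with an estimated correlation the adjusted p was 0.0204 for p53 and senescence and 0.0637 for MHC class I, chemokines, cell cycle, glycolysis and the unfolded protein response.

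Of 9 ventral secretory products 6 fell (7 adjusted over the list alone; median -3.79; camera adjusted p = 2.14e-05, 0.109 with an estimated correlation). Of 20 androgen-responsive genes 4 rose and 8 fell (5 and 8 adjusted over the list alone; limma camera adjusted p = 0.238): the luminal homeobox gene Nkx3-1 fell by 4.19 and Ndrg1 rose by 4.73. The median of that list was -0.10, and 0.87 by total UMIs. Basal keratin markers rose in this class too, 7 of 12 (9 adjusted over the list alone; camera adjusted p = 0.00149, 0.502 with an estimated correlation), with Krt17 (5.51), Lgals7 (4.95), Krt5 (4.52) and Krt14 (4.36), at an estimated 5.77% (median) of free RNA. Luminal progenitor markers rose in 5 of 13 (6 adjusted over the list alone; camera adjusted p = 0.0214, 0.753 with an estimated correlation): Ly6d (4.66), Ly6a (3.45), Wfdc2 (2.70) and Sox9 (0.99). Complement genes rose in 6 of 13, as C3 (5.82) and Cfb (5.58), with an estimated 26.6% of free RNA at the median gene (camera adjusted p = 0.0172, 0.252 with an estimated correlation). Ribosomal protein genes rose in 2 and fell in 15 of 83 (1 and 9 adjusted over the list alone; median -0.42, and 0.47 by total UMIs; camera adjusted p = 0.00149, 0.801 with an estimated correlation). By the edgeR test 2787 genes rose and 2402 fell of 14256, and by total UMIs 9109 rose and 412 fell. Without PTEN intact replicate 1 the total was 3140, against 5189. Shares of luminal clusters differed: clusters 1, 3, 6, 8 and 10 held 33.2, 12.1, 9.49, 5.17 and 9.54% of luminal cells of the intact wild type and 2.92, 0.146, 0.462, 0.486 and 0.0972% of those of intact PTEN mice. Clusters 27, 28, 30 and 36 held 0.0473, 0, 0.0788 and 0% against 24.5, 19.1, 5.54 and 10.8%. Genetic differences between PTEN and wild-type mice other than Pten were not tested, here or in the other cell classes.

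**Figure D1:**
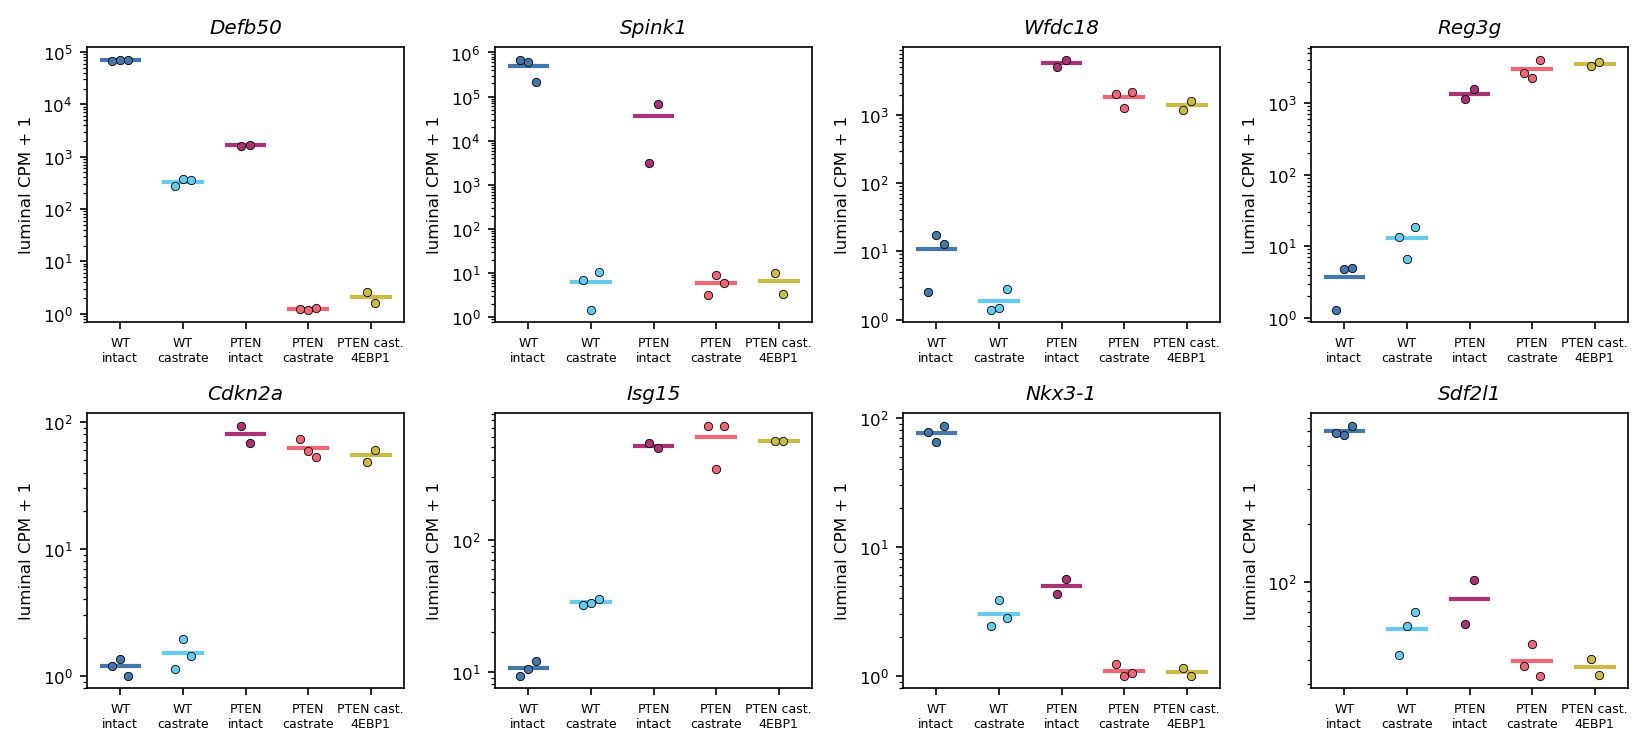
Luminal expression per library (CPM with TMM factors plus 1, logarithmic axis) of 8 named genes in the 5 groups; points are libraries and bars are group means. Defb50 lay near 69179 CPM in the intact wild type and at 0.228 CPM in castrated PTEN mice, while Wfdc18 rose from 9.94 CPM in the intact wild type to 5845 CPM in intact PTEN mice.

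Basal cells of the same groups showed 1271 rises and 1157 falls of 10964 genes (edgeR; 1454 in all without PTEN intact replicate 2, and 314 without genes at 10% or more of free RNA by another estimate, against 2428). Serpinb2, a protease inhibitor of stressed epithelium, was at least 69.3-fold higher, Cdkn2a at least 63.4-fold and the glycosyltransferase gene Galnt6 at least 23.7-fold, each against no UMI in the wild type. Ifi27l2a, an interferon-induced gene, rose from 1.19 ± 1.51 to 328 ± 88.2 CPM (8.02, SE 0.36, edgeR adjusted p = 1.41e-15; 8.29% of free RNA, or 89.6% by another estimate), and Ifi202b rose by 8.34. The neuritin gene Nrn1 fell by 5.30, the carboxypeptidase Scpep1 fell by 3.99, the imprinted Peg10 fell by 3.79 and Rgs16 fell by 3.77. By another estimate free RNA was 37.4% for Cdkn2a, 11.2% for Ifi202b, 12.5% for Nrn1, 25.1% for Rgs16 and 20.9% for Ndufa12. That estimate may be too high here, since cluster 26 had 6 of the markers that set its scale raised. Ndufa12, a subunit gene of respiratory complex I, fell by 4.91 while its processed pseudogene Gm15920 rose by 7.35, and both summed gave -0.55 (edgeR adjusted p = 0.116). Interferon-response genes rose in 17 of 19 (18 adjusted over the list alone; median 3.85, or 3.38 with genes without counts at their bound; camera adjusted p = 2.23e-40, 0.00542 with an estimated correlation), as Rtp4 (7.50) and Bst2 (4.16). MHC class I genes rose in 12 of 13 (camera adjusted p = 9.79e-12, 0.0655 with an estimated correlation). Cell-cycle genes rose in 15 and fell in 2 of 22 (16 and 2 adjusted over the list alone; camera adjusted p = 5.61e-07, 0.251 with an estimated correlation), with Ccna2 (3.30), Ccnb2 (3.17) and Ube2c (2.58). Integrated stress response genes fell in 9 of 14 (1 up and 11 down adjusted over the list alone; camera adjusted p = 0.000109, 0.0367 with an estimated correlation), as Sesn2 (-1.43) and Slc7a11 (-1.33). Genes that dissociation of tissue induces fell in 7 of 17 (1 up and 7 down adjusted over the list alone; camera adjusted p = 0.00229, 0.251 with an estimated correlation), with Ier2 (-1.65) and Junb (-1.64). Cluster 0 held 86% of basal cells in the intact wild type and 3.93% in intact PTEN mice, and cluster 26 held 1.27% and 92.7%.

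Macrophages of intact PTEN mice had 226 genes higher and 204 lower of 6859 than those of the intact wild type (edgeR). The elastase gene Mmp12 fell from 358 ± 117 to 21.8 ± 15.9 CPM (-3.88, SE 0.53, edgeR adjusted p = 0.00205), the integrin gene Itgb8 fell by 3.47, Siglech fell by 3.05, Vmn1r209 fell by 2.90 and the collagen gene Col27a1 fell by 2.73. The histidine-degrading enzyme gene Hal rose by 4.62 and Serpina3g rose by 3.62, and the matrix protein gene Spon1 (at least 7.02-fold), Gpr171 (at least 4.87-fold) and Abhd11 (at least 3.92-fold) had no UMI in the wild type. Interferon genes rose in 13 of 20 (18 adjusted over the list alone; camera adjusted p = 2.4e-22, 0.0312 with an estimated correlation): Irf7 (3.59), Ifit1 (3.57), Rtp4 (2.44) and Zbp1 (2.30). Chemokine and NF-kB genes rose in 1 and fell in 8 of 18 (camera adjusted p = 0.000106, 0.117 with an estimated correlation), with Tnf (-1.70), Cxcl2 (-1.39) and Nfkbiz (-1.10). Dissociation genes moved with them: 1 of 17 fell (median -0.45; camera adjusted p = 0.0227, 0.432 with an estimated correlation). Glycolysis genes rose in 7 of 15 (8 adjusted over the list alone; camera adjusted p = 9.83e-07, 0.117 with an estimated correlation), led by Pgk1 (1.31) and Ldha (1.17). The scavenger receptor gene Cd36 fell by 2.57 and Trem2 rose by 1.01. Mitochondrially encoded RNA fell in 6 of 13 (11 adjusted over the list alone; 42.7% free RNA at the median gene; camera adjusted p = 3.88e-09, 0.117 with an estimated correlation). The total of 430 was 121 without wild-type intact replicate 1, 261 without replicate 2 of that group and 197 without PTEN intact replicate 2.

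Fibroblasts of intact PTEN mice held more RNA of matrix and complement genes than those of the intact wild type: 439 genes rose and 274 fell of 9265 (edgeR). Cluster 7 held 93.6% of fibroblasts in the intact wild type and 23.7% in intact PTEN mice, and cluster 16 held 2.08% and 53.3%. Col10a1, a short-chain collagen of cartilage, rose from 1.28 ± 2.21 to 76.0 ± 20.4 CPM (6.36, SE 0.73, edgeR adjusted p = 2.89e-06), and Ttc9 rose by 6.77. The kininogen gene Kng2 and the phosphatase gene Ptprb (each at least 11.7-fold) and Apol9b (at least 9.57-fold) had no UMI in the wild type. The calcium buffer gene Calb2 was at least 45-fold lower, the prostaglandin synthase Ptgds fell by 4.12, the Notch ligand Dner fell by 4.12 and Npy fell by 4.07. Ndufa12 fell by 4.13 and Gm15920 rose by 6.11 (summed -0.06). Extracellular matrix genes rose in 11 of 16 (12 adjusted over the list alone; camera adjusted p = 2.3e-18, 0.0376 with an estimated correlation), as tenascin Tnc (2.91), Fn1 (2.66) and Bgn (1.76). Complement genes rose in 5 of 11 (7 adjusted over the list alone; camera adjusted p = 1.02e-10, 0.0244 with an estimated correlation), as C4b (3.93) and C3 (2.61). Of 16 growth-factor and steroid-response genes 2 rose and 7 fell (camera adjusted p = 0.000708, 0.128 with an estimated correlation): the Wnt inhibitor Sfrp1 rose by 3.66, the steroid reductase Srd5a2 fell by 3.21, Fgf10 fell by 2.20 and Bmp4 fell by 1.73. Interferon genes rose in 10 of 18 (12 adjusted over the list alone; camera adjusted p = 2.28e-14, 0.115 with an estimated correlation). Secretions of luminal cells fell here too. Their estimated 100% of free RNA follows from the scale, which these secretions set. The total of 713 was 434 without wild-type intact replicate 1 and 403 and 356 without PTEN intact replicates 1 and 2.

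Cell shares of intact PTEN and intact wild-type mice differed in 3 of 13 classes by the edgeR test on cell numbers. In simulated cell numbers with 3 changed classes, that test gave 0.35 false calls per draw. Macrophages made up 15.3 ± 2.51% against 4.40 ± 1.35% of cells (log2 1.80, SE 0.50, edgeR adjusted p = 0.0301), and T or NK cells 8.04 ± 2.02% against 2.20 ± 1.04% (1.87, SE 0.51, edgeR adjusted p = 0.0301), higher in both PTEN libraries than in any wild-type one. Neutrophils were 236 of 11217 cells in intact PTEN and 0 of 13449 in the intact wild type (edgeR adjusted p = 0.0421). With cells of all libraries pooled, a floor of 3 cells allows up to 0.0223% of kept cells there, at least 94.3-fold less. That bound leaves out the spread between libraries. Neutrophils were 26 of 4675 cells (0.556%) in PTEN intact replicate 1 and 210 of 6542 (3.21%) in replicate 2, a mean of 1.88 ± 1.88%. They had a median of 673 and 700.5 UMIs in these libraries, near the minimum of 500, so the bound does not hold for the tissue. Unnamed cells with few UMIs, which were not tested, made up 5.63 and 5.73% in intact PTEN libraries and 0.285, 0.484 and 0.0785% in intact wild-type ones. After castration they made up 7.06, 9.41 and 12.8% in PTEN and 0.717, 0.639 and 1.02% in wild-type libraries. No class passed without wild-type intact replicate 1, without replicate 3 of that group or without PTEN intact replicate 2. Neutrophils did not pass without wild-type intact replicate 2 or by limma on transformed shares either. With at least 1000 UMIs macrophages passed (2.84), while T or NK cells (1.74) and neutrophils did not. Castrated and intact wild-type mice (20.1 ± 14.6% against 11.2 ± 5.53% fibroblasts), castrated and intact PTEN mice (7.75 ± 2.50% against 15.3 ± 2.51% macrophages) and 4EBP1 and castrated PTEN mice (5.66 ± 0.742% against 7.75 ± 2.50% macrophages) gave 0 classes each by edgeR, with 0 at an unadjusted p under 0.05 and 0 by limma on transformed shares. Between castrated PTEN and castrated wild-type mice, basal cells were fewer, 11.7 ± 0.981% against 28.3 ± 5.27% (-1.28, SE 0.34, edgeR adjusted p = 0.0437), which did not pass with TMM factors over classes (-0.63) or with at least 1000 UMIs (-0.78). Neutrophils, 1724 of 17366 against 24 of 13796 cells, did not pass (8.43 ± 9.69% against 0.120 ± 0.207%, edgeR adjusted p = 0.104). The basal difference was lost without any 1 of wild-type castrated replicates 1 (-1.19) and 3 (-1.21) and PTEN castrated replicates 2 (-1.31) and 3 (-1.21), 0 classes each, and 2 and 3 classes passed without wild-type castrated replicate 2 and PTEN castrated replicate 1. Comparisons with the castrated wild type cannot be told apart from a batch of libraries.

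**Figure D2:**
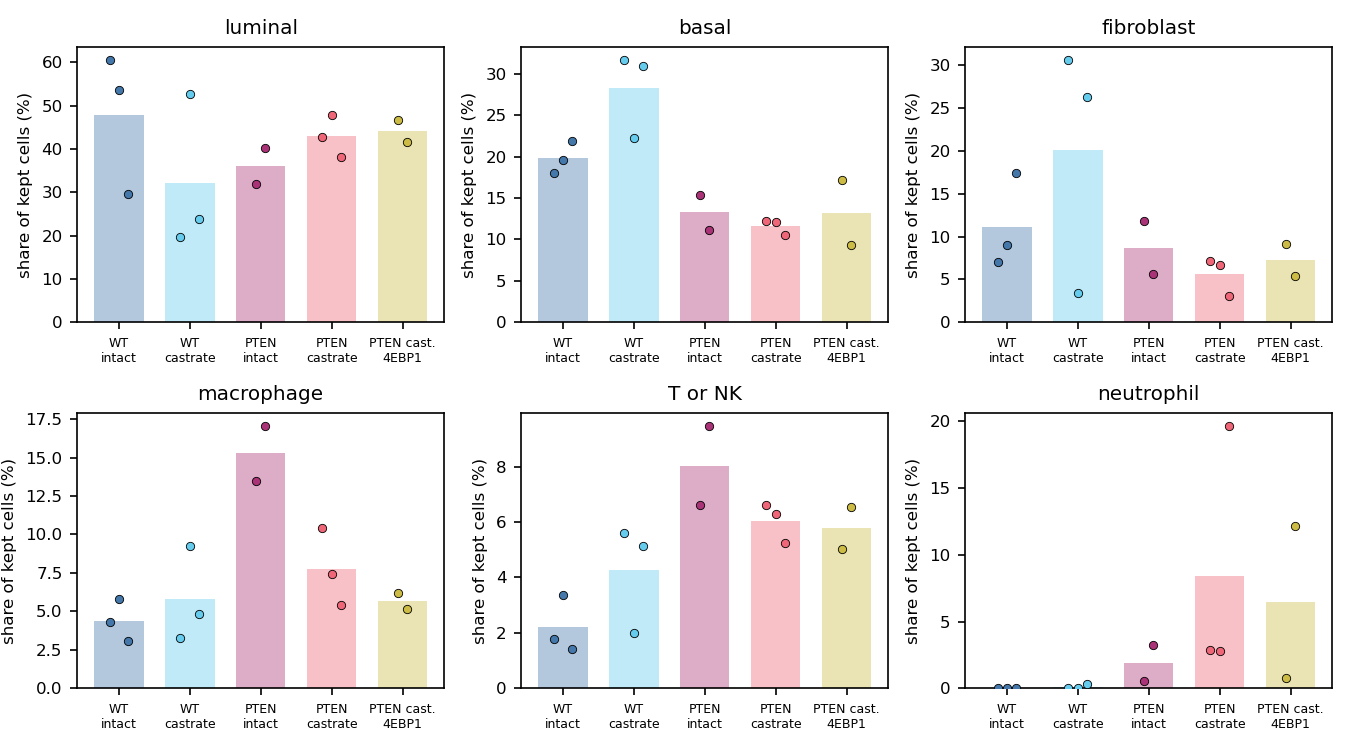
Share of kept cells (%) per library for luminal cells, basal cells, fibroblasts, macrophages, T or NK cells and neutrophils in the 5 groups; points are libraries and bars are group means. Neutrophils averaged 8.43% in castrated PTEN mice with 1 library at 19.6%, and 0% in the intact wild type.

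Castration of wild-type mice (n = 3 and 3), which removes testicular androgen, went with lower RNA of 7 of 9 ventral secretory products in luminal cells. Spink1 fell from 498357 ± 255439 to 5.40 ± 4.67 CPM (-16.28, SE 1.87, edgeR adjusted p = 0.000151), and the spermine-binding protein gene Sbp from 195283 ± 95500 to 16.8 ± 13.7 CPM (-13.39, SE 1.41, edgeR adjusted p = 8.59e-05). The uroplakin gene Upk3a, which codes for a membrane protein of urothelium, rose from 0.327 ± 0.567 to 379 ± 52.3 CPM (11.08, SE 1.17, edgeR adjusted p = 7.64e-05), and the pancreatic-lipase relative Pnliprp1 from 5.27 ± 5.36 to 466 ± 137 CPM (6.78, SE 0.73, edgeR adjusted p = 7.70e-05). The chemokine Cxcl5 rose from 0.419 ± 0.112 to 130 ± 20 CPM (8.21, SE 0.68, edgeR adjusted p = 8.39e-06). The androgen receptor gene Ar rose from 164 ± 10.4 to 348 ± 29.3 CPM (1.08, SE 0.11, edgeR adjusted p = 5.1e-06).

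Androgen-binding-protein genes with no UMI after castration were Scgb2b7 (at least 10679-fold lower), Scgb2b20 (9922), Scgb2b24 (619), Scgb2b17 (243) and Scgb1b7 (235), as was Defb10 (520). Scgb1b20 fell by 13.93 and Wfdc3 fell by 12.43. Further rises were those of the lipase Pnliprp2 (8.63), the adhesion gene Tenm4 (8.54), the ion-transport regulator Fxyd6 (6.26), Sectm1b (5.16), Basp1 (5.12), the semaphorin Sema6a (4.96) and Lce6a (4.89). Of 9 ventral secretory products 7 fell (7 adjusted over the list alone; median -6.36; camera adjusted p = 3.05e-08, 0.105 with an estimated correlation), as Msmb (-10.28), Defb50 (-7.70) and Apof (-5.93). Of 20 androgen-responsive genes 3 rose and 12 fell (median -1.26; camera adjusted p = 0.000385, 0.105 with an estimated correlation): Nkx3-1 fell by 5.37, the peptidase Mme fell by 4.19, the chaperone Fkbp5 fell by 3.88 and Eaf2 fell by 1.76. The unfolded protein response fell in 13 of 14 genes (median -2.17; camera adjusted p = 4.08e-17, 0.115 with an estimated correlation), with Sdf2l1 (-3.41), Pdia6 (-2.77), Pdia4 (-2.52) and calreticulin Calr (-1.73).

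Chemokine and NF-kB genes rose in 12 of 21 (median 1.02; camera adjusted p = 0.000216, 0.654 with an estimated correlation), as Ier3 (2.75), Tnf (2.69), Cxcl16 (2.05) and Icam1 (1.86). Interferon genes rose in 12 and fell in 1 of 20 (limma camera adjusted p = 0.0544): Oasl2 rose by 1.46, Stat1 rose by 1.37 and Mx1 fell by 2.14. The p53 list rose in 7 and fell in 2 of 15, with Cdkn1a (1.79) up. Of 22 cell-cycle genes 8 fell (limma camera adjusted p = 0.127), as the nucleotide reductase Rrm2 (-3.43), and the list's median of -0.47 was 0.55 by total UMIs. Mitochondrially encoded RNA fell in 10 of 13 (11 adjusted over the list alone; median -0.63, and 0.39 by total UMIs; camera adjusted p = 0.0225, 0.946 with an estimated correlation). Markers of luminal cells of other prostate lobes fell in 4 of 6 (5 adjusted over the list alone; camera adjusted p = 0.0195, 0.386 with an estimated correlation), such as Tgm4 (-8.89), which had 182 ± 271 CPM in the intact wild type. Wild-type intact replicate 3 held 707 of 5093 cells (13.9%) in an unnamed cluster rich in Upk2 and 125 seminal vesicle cells (2.45%), while replicates 1 and 2 held 0 and 2 such Upk2-rich cells and no seminal vesicle cell. Castrated wild-type libraries held 2, 16 and 6 seminal vesicle cells (1.28% in replicate 2) and 1, 0 and 2 Upk2-rich cells, and PTEN intact replicate 1 held 197 Upk2-rich cells (4.21%). The edgeR test gave 3380 rises and 3400 falls, and 9296 and 723 by total UMIs. Luminal cells of castrated wild-type mice lay mostly in clusters 34 (70.4%) and 24 (27.9%), which held 0.0631% and 0.284% of those of intact ones. Without the cluster of cells rich in Upk3a and Pnliprp1 (cluster 34), Upk3a no longer passed (3.68) and Pnliprp1 turned to -0.76. Without clusters 3, 10 and 34 Lce6a turned to -0.04 and the total of 6780 was 4398. The castrated wild-type libraries carry other label fields than the rest, so castration and a batch of libraries cannot be told apart from this comparison alone, in this and the other cell classes. Castrated against intact PTEN mice, without that difference in labels, gave falls as well: Spink1 (-12.76), Sbp (-12.89), Nkx3-1 (-5.59) and Fkbp5 (-3.36).

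Basal cells of castrated wild-type mice had 682 genes higher and 806 lower than those of intact ones (edgeR; 388 and 1656 by total UMIs, which moved the median by -0.25; 954 in all without wild-type intact replicate 1, and 370 without genes at 10% or more of free RNA by another estimate, against 1488). The groups lay in different clusters: cluster 0, with Spon2 and Mia among its markers, held 86% of basal cells in intact and 0.214% in castrated wild-type mice, and cluster 29 held 12.7% and 99.2%. The annexin gene Anxa8 rose from 1.59 ± 1.15 to 38.9 ± 10.5 CPM (4.65, SE 0.43, edgeR adjusted p = 9.49e-09), involucrin Ivl, a protein of cornified epithelium, rose by 3.71, the water channel Aqp3 rose by 3.49, Elobl rose by 3.38 and the activin inhibitor Fst rose by 3.32. The matrix protein gene Spon2 fell from 274 ± 77.3 to 5.19 ± 1.06 CPM (-5.65, SE 0.38, edgeR adjusted p = 5.55e-09), Mia fell by 4.89, the retinal dehydrogenase Aldh1a7 fell by 4.81, versican Vcan fell by 3.92 and the phosphatase Alpl fell by 3.78. Ribosomal protein genes rose in 33 and fell in 1 of 82 (38 and 1 adjusted over the list alone; median 0.46, and 0.23 by total UMIs; camera adjusted p = 3.27e-13, 0.329 with an estimated correlation), as Rps5 (1.40) and Rps15 (1.30). Translation factors whose messages begin with an oligopyrimidine tract rose in 8 of 15 (10 adjusted over the list alone; camera adjusted p = 3.83e-07, 0.138 with an estimated correlation), as Eef1d (1.74) and Rack1 (1.05). Androgen-responsive genes rose in 2 and fell in 7 of 19 (2 and 8 adjusted over the list alone; camera adjusted p = 0.0282, 0.183 with an estimated correlation): Fkbp5 fell by 1.74 while Ndrg1 rose by 1.45. Mitochondrially encoded RNA fell in 10 of 13 (13 adjusted over the list alone; median -0.97; 27.8% free RNA at the median gene; camera adjusted p = 1.4e-10, 0.138 with an estimated correlation).

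Fibroblasts of castrated wild-type mice held less matrix RNA than those of intact ones. By edgeR 227 genes rose and 340 fell (192 and 497 by total UMIs, which moved the median by -0.12). Matrix genes fell in 11 of 16 (12 adjusted over the list alone, median -1.67, camera adjusted p = 4.22e-15, 0.0727 with an estimated correlation), with Sparc (-2.15), Col6a3 (-2.11), Col5a2 (-2.00) and Col1a1 (-1.59). Cluster 7 held 93.6% of fibroblasts in intact and 40.7% in castrated wild-type mice. A change of cluster shares was not separated from a change of matrix RNA within cells. The complement gene C7 was at least 55-fold lower, Calb2 fell by 7.32, the Wnt-induced Ccn5 fell by 6.13, osteopontin Spp1 fell by 5.42 and Ptgds fell by 4.87. Igfbp3, which binds insulin-like growth factors, rose from 95.9 ± 24.2 to 1669 ± 1301 CPM (4.22, SE 0.64, edgeR adjusted p = 0.0053), Thy1 rose by 3.81, H2-Q6 rose by 3.00, the cytokine Il34 rose by 2.55 and the peptide hormone gene Apela rose by 2.52. Growth-factor and steroid-response genes fell in 5 of 16 (3 up and 6 down adjusted over the list alone; camera adjusted p = 0.00744, 0.105 with an estimated correlation): Bmp5 fell by 4.46, Igf1 fell by 3.04 and Fgf10 fell by 2.35. A cluster that held nearly only cells of wild-type castrated replicates 1 and 3 carried part of this, as the total of 567 was 337 without it and Il34 turned to -0.36. The total was 297 and 371 without wild-type intact replicates 1 and 2, and 261 and 211 without wild-type castrated replicates 1 and 3.

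Macrophages of castrated wild-type mice had 60 genes higher and 35 lower (edgeR; 39 and 50 by total UMIs, which moved the median by -0.11). The adhesion gene Vcam1 rose from 44.6 ± 24.4 to 271 ± 30.2 CPM (2.71, SE 0.43, edgeR adjusted p = 0.00258), the MHC-like H2-M2 rose by 3.97, Olfml3 rose by 3.10, B3gat3 rose by 2.67 and the zinc transporter Slc39a13 rose by 2.43. Zfp84 fell by 2.96, Tmprss11a fell by 2.92, the actin-binding Lsp1 fell by 2.26, Tnfsf9 fell by 2.18 and Cdk6 fell by 2.09. Of 13 genes of lipid-associated macrophages 4 rose (5 up and 1 down adjusted over the list alone; camera adjusted p = 1.3e-05, 0.071 with an estimated correlation): the lipid receptor Trem2 (1.69), cathepsin Ctsd (1.55), Apoe (1.34) and Cd63 (0.67). Il10 (1.91) and Il1b (1.11) were the 2 of 11 myeloid suppressor genes that rose (4 adjusted over the list alone; camera adjusted p = 0.000274, 0.0615 with an estimated correlation). The total of 95 was 42 and 51 without wild-type intact replicates 1 and 2 and 45 without wild-type castrated replicate 3.

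Castration of PTEN mice (n = 3 and 2) asked how the PTEN epithelium responds to androgen loss, and the secretory genes fell further. Clusters 30 and 36 held 30.9% and 27.7% of luminal cells in castrated and 5.54% and 10.8% in intact PTEN mice, while clusters 2 and 22 held none and 19.2% and 13.4%. Defb50 fell from 1639 ± 23.1 to 0.228 ± 0.0458 CPM (-12.68, SE 0.33, edgeR adjusted p = 6.75e-12). Sbp fell by 12.89 and Spink1 fell by 12.76, both from a wide spread in intact PTEN mice (17015 ± 16075 and 35935 ± 46326 CPM). The kallikrein Klk1b16, a serine protease, rose from 0.149 ± 0.211 to 60.7 ± 16.2 CPM (8.17, SE 0.47, edgeR adjusted p = 4.13e-06). The B-cell chemokine Cxcl13 rose from 1.78 ± 1.12 to 34.7 ± 8.30 CPM (4.14, SE 0.40, edgeR adjusted p = 6.67e-05) and the growth factor Tgfb2 from 4.67 ± 1.19 to 46.3 ± 9.59 CPM (3.35, SE 0.30, edgeR adjusted p = 3.06e-05).

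Other luminal rises were trypsin Prss2 (5.12), Scgb1c1 (4.88), the actin regulator Phactr1 (4.35), Fxyd2 (3.80), haptoglobin Hp (3.51), the mucin Muc13 (3.46) and Clca3a2 (3.41). The glycosyltransferase gene Abo was at least 1028-fold lower, retinoic-acid-binding Crabp1 fell by 10.73, the protease inhibitor Spink5 fell by 9.10, Mroh4 fell by 7.03, Wfdc3 fell by 6.39, Reg3b fell by 6.23 and Scgb2b27 fell by 6.16. All 9 ventral secretory products fell (median -5.10; camera adjusted p = 5.63e-35, 0.00221 with an estimated correlation), as Azgp1 (-5.10) and Apof (-4.65). Of 20 androgen-responsive genes 1 rose and 10 fell (4 and 10 adjusted over the list alone; median -0.51; camera adjusted p = 1.16e-06, 0.0124 with an estimated correlation): Zbtb16 fell by 8.11, Nkx3-1 fell by 5.59, Fkbp5 fell by 3.36 and Mme fell by 3.21. Unfolded protein response genes fell in 6 of 14 (7 adjusted over the list alone; median -0.49; camera adjusted p = 0.000716, 0.805 with an estimated correlation), as Herpud1 (-1.20) and Sdf2l1 (-1.08). Complement genes rose in 3 of 13 (3 up and 1 down adjusted over the list alone; 25.9% free RNA at the median gene; camera adjusted p = 0.00869, 0.303 with an estimated correlation): C3 (2.19), Cfh (2.04) and C4b (1.90). Of 21 chemokine and NF-kB genes 3 rose, among them Cxcl5 (2.02) and Icam1 (1.10) (camera adjusted p = 0.0476, 0.909 with an estimated correlation). Markers of other cells rose too: the pericyte gene Rgs5 (5.17), the T-cell receptor gene Trbc2 (2.95) and the neutrophil gene S100a9 (2.95, an estimated 100% of free RNA). The scale of that estimate was set with neutrophil markers, so it cannot tell whether luminal cells held S100a9 RNA. By the edgeR test 432 genes rose and 588 fell, and by total UMIs 394 and 353. The total of 1020 was 194 without PTEN intact replicate 2, 605 and 468 without PTEN castrated replicates 1 and 3.

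The luminal response to castration differed between PTEN and wild-type mice in 2854 genes by the edgeR interaction test, 1242 with a higher and 1612 with a lower change in PTEN mice. Defb50 fell by 12.68 in PTEN and by 7.70 in wild-type mice (fell by 4.98 more, SE 0.36, edgeR adjusted p = 6.8e-06). Cxcl5 differed by -6.19 (SE 0.83, edgeR adjusted p = 0.00122) and Sectm1b by -5.81 (SE 0.40, edgeR adjusted p = 6.8e-06), and the acid phosphatase Acp5 by 4.12 (SE 0.31, edgeR adjusted p = 8.28e-06). Ar differed by -0.79 (SE 0.17, edgeR adjusted p = 0.00531), with a rise of 1.08 in the wild type and 0.29 in PTEN mice (edgeR adjusted p = 0.203). Further genes with a higher change in PTEN mice were Pcp4 (8.49), the protease inhibitor Mug1 (6.19), Wfdc3 (6.04), Prss2 (5.83), Rnf186 (5.58), the arginine enzyme Ass1 (4.44), the phospholipase Pla2g4a (4.21), the kinetochore gene Spc25 (4.10) and Dcaf12l1 (4.09). Olfm4 had a lower change too, with no exact value since the intact wild type had no UMI. Other lower changes were those of Pnliprp2 (-8.01), Lce6a (-7.57), Zbtb16 (-6.38), Tenm4 (-5.95), Pnliprp1 (-5.11) and the protease Mmp7 (-4.98). Unfolded protein response genes fell less in PTEN mice, 12 of 14 (13 adjusted over the list alone; median 1.62, and 0.74 by total UMIs; camera adjusted p = 1.22e-13, 0.533 with an estimated correlation), with Sdf2l1 (2.33), Pdia4 (2.22) and Pdia6 (2.08). Of 21 chemokine and NF-kB genes 6 changed less (8 adjusted over the list alone; median -0.90; camera adjusted p = 0.00196, 0.98 with an estimated correlation), as Tnf (-2.32), Cxcl16 (-2.10) and Relb (-1.46). Cell-cycle genes had a higher change in 5 of 22 (6 adjusted over the list alone; camera adjusted p = 0.0264, 0.98 with an estimated correlation), as Rrm2 (2.29) and Cdk1 (1.71), and their median of 0.55 was -0.37 by total UMIs. By total UMIs 236 and 6730 genes passed. The total of 2854 was 1721 without PTEN intact replicate 1, 1410 without cluster 34 and 784 without clusters 3, 10 and 34. Without cluster 34 Pnliprp1 turned to 2.46 and Tenm4 no longer passed (-1.62), while Cxcl5 gave -8.12 and Ar -1.23. Levels before castration differed already, as given above. Unfolded protein response genes and Pcp4 were lower, and Cxcl5 was higher, in intact PTEN than in intact wild-type mice. The interaction cannot tell such a different start from a different response to castration. The castrated wild-type libraries carry other label fields than the rest, so a difference in response and a batch of libraries cannot be told apart.

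In other cells of castrated against intact PTEN mice, basal cells had 124 genes higher and 148 lower (edgeR), with the hyaluronan synthase Has2 (2.34), Spp1 (2.13) and Cpa6 (2.07) up. Col14a1 (2.82), a marker of a fibroblast cluster, and Rgs5 (2.99), a marker of smooth muscle, rose too. By another estimate free RNA was 100% for Spp1, 10.1% for Cpa6, 12.4% for Col14a1 and 35.4% for Rgs5. That estimate may be too high, since markers that set its scale were raised in cluster 26, which held most of these basal cells. In these cells Aldh1a7 fell by 3.80 (17.7%), Coro2a fell by 3.33 (45.0%) and the defensin Defb2 fell by 3.31. Mmp7 fell by 4.35 and Ccl5 fell by 2.96, both at 100% of free RNA by another estimate. Basal androgen-responsive genes fell in 5 of 19 (1 up and 7 down adjusted over the list alone; camera adjusted p = 1.97e-06, 0.0144 with an estimated correlation), as Zbtb16 (-4.37), Fkbp5 (-2.92) and Mme (-2.85). The basal total of 272 was 105 without genes at 10% or more by that estimate, 109 without PTEN intact replicate 2 and 154 without PTEN castrated replicate 3. Macrophages had 22 genes higher and 61 lower. The lectin Clec10a of alternatively activated macrophages fell from 196 ± 32.8 to 32.6 ± 6.71 CPM (-2.62, SE 0.28, edgeR adjusted p = 2.79e-06), the leukotriene synthase Ltc4s fell by 2.39, the lipase Pla2g2d fell by 2.99, Tslp fell by 2.98 and complement C6 fell by 2.86. G0s2 rose by 3.56 (18.7% of free RNA by another estimate), while the neutrophil genes S100a8 (4.17, edgeR adjusted p = 0.367) and S100a9 (5.05, edgeR adjusted p = 0.39) were higher in each castrated library and did not pass. Cst7 rose by 1.99, Cmpk2 rose by 1.89, the itaconate enzyme Acod1 rose by 1.64 and Cxcl14 rose by 1.60. No gene of 11 in the list of alternatively activated macrophages passed over all genes, and 8 fell when adjusted over the list alone (median -2.27; camera adjusted p = 3.24e-11, 0.144 with an estimated correlation). Dissociation genes fell in 3 of 17 there (10 adjusted over the list alone; camera adjusted p = 4.58e-07, 0.162 with an estimated correlation). The macrophage total of 83 was 147 and 7 without PTEN intact replicates 1 and 2, 36 and 16 without PTEN castrated replicates 1 and 3, and 16 without cluster 13, which has Clec10a among its markers and held 20.3% of macrophages in intact and 3.96% in castrated PTEN mice. Without it Clec10a (-1.31), Ltc4s (-0.74), Pla2g2d (-0.82), Cst7 (1.68) and Cxcl14 (1.33) no longer passed.

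Fibroblasts of castrated PTEN mice had 15 genes higher and 41 lower than those of intact PTEN mice (edgeR). The estrogen-inactivating sulfotransferase gene Sult1e1 fell from 428 ± 152 to 6.11 ± 3.34 CPM (-6.05, SE 0.49, edgeR adjusted p = 1.74e-06), C7 fell by 4.70, the collagen Col6a5 fell by 4.62, Hp fell by 3.47 and Tnmd fell by 3.40. The chitinase-like Chil1 rose by 3.36, the prostaglandin receptor Ptger3 rose by 2.26 and Unc5c rose by 2.12. The neutrophil genes S100a8 (2.45) and S100a9 (2.37) rose as well, at 29.5% and 44.0% of free RNA by another estimate. The total of 56 was 103 and 11 without PTEN intact replicates 1 and 2 and 14 without PTEN castrated replicate 3.

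Castrated PTEN against castrated wild-type mice (n = 3 and 3), which compares PTEN status at low androgen, gave 2844 luminal rises and 2753 falls (edgeR). The castrated wild-type libraries carry other label fields than the rest, so PTEN status and a batch of libraries cannot be told apart from this comparison alone. The intact groups, without that difference in labels, gave a rise of Wfdc18 by 9.28 and interferon and MHC class I medians of 4.18 and 1.82. In both comparisons PTEN and wild-type mice also differed in counts of Ndufa12 and Gm15920, given below. Other genetic differences between these mice were not tested, so PTEN status cannot be told apart from them. Wfdc18 had 1819 ± 467 against 0.895 ± 0.804 CPM (10.73, SE 0.98, edgeR adjusted p = 3.86e-05), Reg3g 2992 ± 970 against 11.9 ± 6.06 CPM (7.88, SE 0.70, edgeR adjusted p = 2.67e-05) and Oas2, an interferon-induced synthetase, 61.9 ± 4.21 against 0.273 ± 0.180 CPM (8.12, SE 0.36, edgeR adjusted p = 1.46e-09). Pnliprp1 had 2.81 ± 0.161 against 466 ± 137 CPM (-7.37, SE 0.72, edgeR adjusted p = 5.82e-05). Without cluster 34, found mostly in the castrated wild type, Pnliprp1 gave 0.10. Ar was lower in PTEN mice (-0.76, SE 0.11, edgeR adjusted p = 0.00012). Ifi202b (at least 705-fold), the hypoxia-induced Ndufa4l2 (317) and Lypd8 (169) had no UMI in the castrated wild type. Klk1b16 (9.87), the arginine deiminase Padi4 (7.84), the steroid dehydrogenase Hsd11b2 (7.61) and keratin Krt13 (7.38) were higher, and Pnliprp2 (-7.44), the gluconeogenic Fbp1 (-7.06), Lce6a (-6.76), Rnase1 (-6.58), Defb1 (-6.02), Tmem45a (-5.51), Bex4 (-5.50) and Slc22a1 (-5.37) lower. Pate4, a marker of the seminal vesicle cluster, was lower too (-13.47). Pate4 did not pass without cluster 34 (-7.30) or without PTEN castrated replicates 2 (-13.16) or 3 (-14.80). Castrated wild-type libraries held 2, 16 and 6 seminal vesicle cells and PTEN libraries held none.

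All 20 interferon genes were higher in castrated PTEN mice (median 3.87; camera adjusted p = 3.78e-46, 0.00318 with an estimated correlation), as Mx1 (4.92) and Bst2 (3.51), and all 13 MHC class I genes (median 1.64; camera adjusted p = 4.5e-14, 0.0691 with an estimated correlation), as H2-Q7 (3.69). Higher too were 15 of 21 chemokine genes (camera adjusted p = 1.17e-05, 0.218 with an estimated correlation), 10 of 15 p53 genes (10 up and 1 down adjusted over the list alone; camera adjusted p = 1.17e-05, 0.0691 with an estimated correlation), with Cdkn2a (7.33), and 6 of 13 complement genes (camera adjusted p = 0.00129, 0.0431 with an estimated correlation), with Cfb (6.30) and C3 (5.31). Cell-cycle genes were higher in 20 of 22 (22 adjusted over the list alone; median 1.95; camera adjusted p = 3.95e-15, 0.0431 with an estimated correlation), as Cdk1 (3.73), Rrm2 (3.25) and Birc5 (2.21), and all 15 glycolysis genes were (median 1.61; camera adjusted p = 4.01e-17, 0.0431 with an estimated correlation), as Slc16a3 (3.69) and Pgk1 (2.43). Secretory products were lower in 7 of 9 (camera adjusted p = 9.23e-07, 0.0691 with an estimated correlation), as Defb50 (-10.38) and Pbsn (-7.36), and 6 of 20 androgen-responsive genes were higher and 7 lower (7 and 8 adjusted over the list alone). Mitochondrially encoded RNA was higher in 9 of 13 (11 adjusted over the list alone; median 0.84; camera adjusted p = 0.00771, 0.867 with an estimated correlation).

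**Figure D3:**
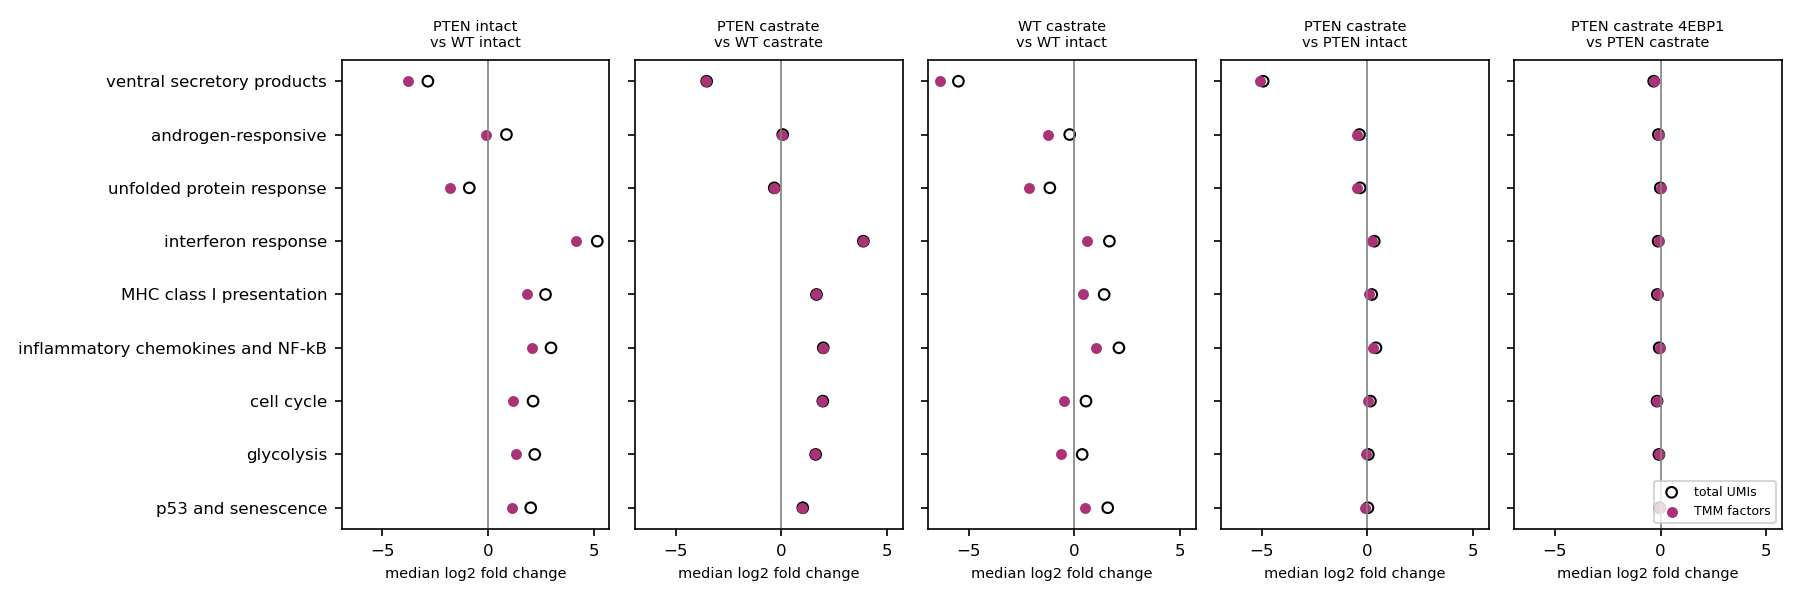
Median log2 fold change in luminal cells of 9 gene lists in the 5 group comparisons, with TMM factors (filled points) and with total UMIs alone (open points). The interferon list lay at 4.18 and 3.87 where PTEN and wild-type mice were compared. The androgen-responsive list turned from -0.10 to 0.87 by total UMIs in the intact comparison, and after castration of the wild type cell cycle turned from -0.47 to 0.55 and glycolysis from -0.64 to 0.37.

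Castrated PTEN mice with 4EBP1 and doxycycline against those without (n = 2 and 3), which compares libraries labelled 4EBP1 with the other castrated PTEN libraries, gave 0 luminal genes by edgeR (305 at an unadjusted p under 0.05), 2 by DESeq2, and 1 by edgeR without PTEN castrated replicate 3. Eif4ebp1 itself had 82.2 ± 7.02 against 85.7 ± 7.74 CPM (-0.06, SE 0.30, edgeR adjusted p = 1), where RNA of a transgene is counted only if it shares the 3-prime end of the gene. Camera called luminal lists without a single gene passing: cell cycle (median -0.15; adjusted p = 0.000797, 0.489 with an estimated correlation), ribosomal proteins (median -0.08; adjusted p = 0.00468, 0.814 with an estimated correlation), complement (median -0.19; adjusted p = 0.000162, 0.15 with an estimated correlation) and cholesterol synthesis (median 0.17; adjusted p = 0.00151, 0.814 with an estimated correlation). Macrophage markers (median -0.76) and neutrophil markers (median -0.90) moved with them, and so did dissociation genes (median 0.17, camera adjusted p = 0.00468, 0.644 with an estimated correlation). Free RNA was put at 100% and 86% for these macrophage and neutrophil markers. They set the scale of that estimate, so it cannot show whether their RNA was free. In fibroblasts Col10a1 fell from 115 ± 42.5 to 0.972 ± 1.37 CPM (-6.60, SE 0.72, edgeR adjusted p = 1.52e-05), the 1 gene that passed. Without PTEN castrated replicate 2, 3 genes passed. Cluster 7 held 29.7% of fibroblasts in 4EBP1 and 7.4% in castrated PTEN libraries. A change of cluster shares was not separated from a change within cells. In macrophages the kinase gene Wnk1 fell from 323 ± 11.6 to 143 ± 21.2 CPM (-1.18, SE 0.20, edgeR adjusted p = 0.0162) and none passed without any 1 of the 5 libraries. Alternatively activated macrophage genes had a median of 0.97 (0 passed; camera adjusted p = 8.77e-06, 0.97 with an estimated correlation). In basal cells 2 genes rose, 1 without genes at 10% or more of free RNA by another estimate, and 0 without any 1 of the PTEN castrated replicates or 4EBP1 replicate 1. Doxycycline and 4EBP1 cannot be told apart, as no library has 1 without the other.

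Of the targeted genes, luminal Pten (chromosome 19, 32757497 to 32826160) had 51.0 ± 4.42 CPM in the intact and 63.0 ± 7.56 in the castrated wild type, 38.8 ± 3.72 in intact PTEN, 39.7 ± 2.16 in castrated PTEN and 39.1 ± 3.11 in 4EBP1 libraries. It fell by 0.39 in intact PTEN against intact wild-type mice (SE 0.14, edgeR adjusted p = 0.0368), which total UMIs turned to 0.50. That call was lost without count filter (-0.32), with the groups compared alone (-0.40), without clusters 3, 10 and 34 (-0.30), and without wild-type intact replicates 2 (-0.39) or 3 (-0.33) or PTEN intact replicates 1 (-0.48) or 2 (-0.28). Between the castrated groups Pten fell by 0.65 (SE 0.12, edgeR adjusted p = 0.000678). The 3-prime end that was counted may lie outside the deleted part. Eif4ebp1 (chromosome 8, 27260329 to 27276674) was highest in the intact wild type, 596 ± 179 CPM, and had 197 ± 102 CPM in intact PTEN (-1.60, SE 0.32, edgeR adjusted p = 0.00217) and 131 ± 17.8 CPM in castrated wild-type mice (-2.19, SE 0.28, edgeR adjusted p = 6.16e-05). Total UMIs moved the median of all luminal genes by 0.93 and 1.04 in these 2 comparisons, so both falls are smaller by total UMIs. On that scale PTEN intact replicate 2 (4504 of 15719419 luminal UMIs) was not below wild-type intact replicate 3 (1190 of 4235181). In castrated PTEN mice Eif4ebp1 had 85.7 ± 7.74 CPM, lower than in intact ones (-1.20, SE 0.30, edgeR adjusted p = 0.0307). Ar did not pass between intact PTEN and wild-type mice with TMM factors (0.04, SE 0.13, edgeR adjusted p = 0.855), and gave 0.92 by total UMIs, which passed.

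**Figure D4:**
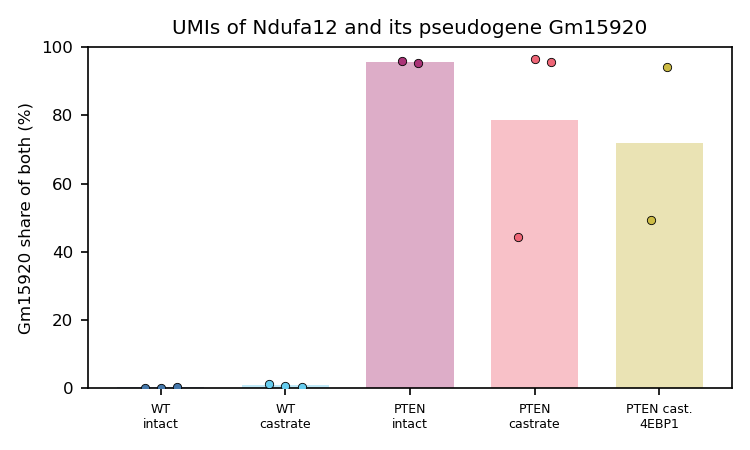
Share of Gm15920 in the UMIs of Ndufa12 and Gm15920 together (%) over kept cells, per library; points are libraries and bars are group means. Wild-type libraries lay at 0.152% to 1.28% and PTEN castrated replicate 1 at 44.2%.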

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

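Tests of the summed Ndufa12 counts, with TMM factors and by total UMIs, of the deletion of Pten as a cause and of depth for rtTA were chosen after the result was seen. The castration response of luminal cells differed between PTEN and wild-type mice in 2854 genes by the edgeR interaction test. The transgene rtTA_eGFP, a doxycycline-controlled activator, had 1354 UMIs over all barcodes of intact PTEN, 2231 of castrated PTEN and 113 of 4EBP1 libraries. Cre recombinase had 22 UMIs in intact PTEN libraries. Wild-type libraries held 12, 2, 1, 1, 0 and 2 rtTA_eGFP UMIs, none in kept cells.

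Ndufa12 (chromosome 10, 94198720 to 94221443) was nearly absent in luminal cells of intact PTEN mice (-5.26, SE 1.48, edgeR adjusted p = 0.0238), while its processed pseudogene Gm15920 (chromosome 5, 130188395 to 130188796) rose by 8.61. Summed, both changed by -0.71 in luminal cells (SE 0.18, edgeR adjusted p = 0.00604), which total UMIs turned to 0.20 (SE 0.19, edgeR adjusted p = 0.366), and by -0.55, -0.07 and -0.06 in basal cells, macrophages and fibroblasts. The fall of 1 gene and the rise of the other thus nearly cancel. Mixing of mice with and without the pattern was excluded, since the lowest ratio of observed to expected cells with UMIs of both genes was 1.13. The pseudogene share ranged over 52.2 percentage points within castrated PTEN libraries (44.2, 96.4 and 95.5%) and was 49.3 and 94.2% in 4EBP1 libraries. This argues against deletion of Pten as the cause without excluding it. The limit of that test was set after the shares were seen, and the range rests on 1 castrated PTEN library. A strain variant of Ndufa12 could produce the pattern and was not tested. If PTEN and wild-type mice differ in such variants, comparisons between them cannot tell PTEN status from genetic background.

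In luminal cells rtTA_eGFP had 2.61 ± 1.19 CPM in 4EBP1 and 37 ± 13.8 CPM in castrated PTEN libraries (-3.90, SE 0.53, edgeR adjusted p = 0.744). The difference did not pass the edgeR test. Lower depth did not account for it, with at most 0.103 of the UMIs that depth would give. CPM already divides by depth, so that test could not have come out otherwise. Another mix of luminal clusters was excluded, since the median over clusters was -3.69 (from -4.92 to -3.25). Silencing of the construct, a different construct in the 4EBP1 mice and an effect of doxycycline may each produce it and stay open.

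Neutrophils were 236 of 11217 cells in intact PTEN and 0 of 13449 in intact wild-type mice. For S100a8 and S100a9, the genes set for this test, depth was excluded as the cause of their difference in UMIs. Over all barcodes they were 34.6-fold higher (345 ± 69.3 against 9.97 ± 0.646 at equal total UMIs, where depth allowed less than 4-fold). Both genes also led an unnamed cluster with luminal and basal markers raised, so their UMIs need not come from neutrophils. Whether depth hid neutrophils in the wild type thus stays open. Csf3r, Cxcr2, Retnlg and Il1r2 together had 47.3 ± 4.81 against 12.3 ± 2.22, a log2 change of 1.94 that stayed below 4-fold. Their values at equal total UMIs did not overlap, with 50.7 and 43.9 in intact PTEN against 10.5 to 14.8 in intact wild-type libraries. As their change stayed within the limit set for depth, it does not exclude depth for these genes. Macrophages, a larger share of cells in intact PTEN mice, also held UMIs of Csf3r. Haemoglobin changed by 0.37 on the log2 scale while S100a8 and S100a9 changed by 5.11, so haemoglobin did not rise to the same extent. At equal total UMIs it had 4347, 4794 and 10439 in intact wild-type and 8024 and 8861 in intact PTEN libraries. Haemoglobin follows red cells, so this test cannot tell whether neutrophils came with blood. Blood left in the tissue stays open. Infiltration was not tested and stays open.

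The 6 libraries of a comparison of 3 and 3 give 10 splits, too few for a share under 0.05. In luminal cells 1 of 10 splits, the real one, reached 6780 genes for castration of the wild type (highest other 0) and 1 reached 5597 between the castrated groups (highest other 0). Highest others were 2 for 1488 basal genes, 1 for 95 macrophage genes and 43 for 567 fibroblast genes. Composition after castration of the wild type gave 0 classes in all 10 splits, and between the castrated groups 1 class against 0.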

How the results depend on the processing

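Before the data were examined, the comparisons, the tests, the gene lists, the naming rule and these alternatives were fixed: RLE, no count filter, DESeq2, 1000 UMIs, 10% mitochondrial UMIs, doublets kept, the replicate block, the groups compared alone, an estimated correlation and each library left out. Total UMIs, the second estimate of free RNA, clusters left out and library changes for lists were chosen after the result was seen. The cause of a difference was not tested unless said. Called genes named for the comparisons kept their call and direction under RLE in 942 of 948, under total UMIs in 846 (29 reversed), without count filter in 902, with DESeq2 in 877, and with the replicate block in 891. They did so in 839 of 938 with at least 1000 UMIs, 803 of 911 with the groups compared alone, 405 of 527 without cluster 34 (19 reversed), 361 of 521 without clusters 3, 10 and 34 (22 reversed) and 369 of 523 without PTEN intact replicate 2.

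In luminal cells 5189 genes of intact PTEN against intact wild type became 9521 by total UMIs, and 2854 of the interaction became 6966, since Spink1 and few other secretions take much of the wild-type UMIs. The sum of Ndufa12 and Gm15920 turned from -0.71 to 0.20 by total UMIs, for the same reason. Pten turned from -0.39 to 0.50 by total UMIs; it was -0.32 without count filter, -0.40 with the groups alone and -0.30 without clusters 3, 10 and 34, none of these passing, and -0.28 to -0.48 with a library left out. The interaction gave 1410 genes without cluster 34 and 784 without clusters 3, 10 and 34, and castration of the wild type 4398 without these. Pnliprp1 turned from 6.78 to -0.76 after castration of the wild type, from -7.37 to 0.10 between the castrated groups and from -5.11 to 2.46 in the interaction without cluster 34, because that cluster holds its counts. Lce6a turned from 4.89 to -0.04 without clusters 3, 10 and 34. For 4EBP1 against castrated PTEN 0 luminal genes became 2 with DESeq2 and 1 with the replicate block.

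Basal cells of castrated against intact PTEN gave 410 genes without count filter and 177 with DESeq2, against 272. For 4EBP1 2 genes became 8 without count filter, and 0 with DESeq2 or the replicate block. Leaving out genes with 10% or more free RNA by the second estimate, basal counts were 314 (of 2428), 370 (of 1488), 105 (of 272) and 1 (of 2) in intact PTEN, castrated wild type, castrated PTEN and 4EBP1. That estimate may be too high in basal cells of PTEN mice, so the counts with PTEN libraries may be too low. Macrophages gave 660, 158, 220 and 3 genes without count filter against 430, 95, 83 and 1 in the same order, 51 with DESeq2 for castrated PTEN, and 161, 59 and 0 with at least 1000 UMIs for intact PTEN, castrated wild type and 4EBP1. Castrated against intact PTEN gave 16 without macrophage cluster 13.

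Fibroblasts gave 169 genes without count filter for castrated against intact PTEN and 28 for 4EBP1, against 56 and 1. DESeq2 gave 337, 288 and 27 against 713, 567 and 56, and at least 1000 UMIs 416 and 370 for the first comparisons, intact PTEN and castrated wild type. With the groups compared alone castration of the wild type gave 351, castration of PTEN 35 and 4EBP1 2, and the replicate block gave 2 for 4EBP1. Without fibroblast cluster 25 castration of the wild type gave 337, and Il34 turned from 2.55 to -0.36, because that cluster holds its counts.

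Cell shares between castrated PTEN and castrated wild type gave 0 classes with TMM factors or at least 1000 UMIs, 2 with doublets kept and 3 with the replicate block, against 1. Intact PTEN against intact wild type gave 1 class with at least 1000 UMIs, against 3. Gene lists passing with an estimated correlation were 8 of 48 in luminal cells, 6 of 38 in basal cells, 4 of 30 in macrophages and 3 of 39 in fibroblasts. With 1 library left out of a group of 3, the fewest list calls kept were 45 luminal (without PTEN castrated replicate 1) and 33 basal (wild-type castrated replicate 3). They were 25 in macrophages (wild-type intact replicate 3) and 31 in fibroblasts (PTEN castrated replicates 1 or 3). Correlations of libraries with the same number ran from -0.44 to 0.25 and did not pass 0.1 in each pair of any comparison of 3 pairs, so the numbers were not used as pairs. In fibroblasts of castrated and intact wild type each library correlated best with its own number (0.05, 0.02 and 0.03, against -0.04 to 0 for other pairs), a hint from the data, and the block gave 593 genes there against 567. In fibroblasts of intact PTEN and wild type the 2 pairs of the same number also exceeded the others. With 2 PTEN libraries each correlation of 1 is that of the other with its sign turned, so this is no further hint. Deviations from group means sum to 0, which ties the correlations of 3 libraries too, so their order is weak evidence.

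With each library left out in turn, luminal genes ranged over 3140 to 5745 for intact PTEN, 5522 to 7125 for castrated wild type, 194 to 1355 for castrated PTEN, 0 to 1 for 4EBP1, 4441 to 5147 between the castrated groups and 1721 to 3708 for the interaction. Single values past a factor of 1.5 were 605 and 468 luminal genes without PTEN castrated replicates 1 and 3. Basal genes ranged over 1454 to 2180, 954 to 1530, 109 to 208 (154 without PTEN castrated replicate 3) and 0 to 2. Macrophage genes ranged over 121 to 351 (261 and 197 without wild-type intact 2 and PTEN intact 2), 42 to 87 (51 and 45 without wild-type intact 2 and wild-type castrated 3), 7 to 147 (36 and 16 without PTEN castrated 1 and 3) and 0 to 0. Fibroblast genes ranged over 356 to 603 (434 and 403 without wild-type intact 1 and PTEN intact 1), 211 to 669 (297, 371 and 261 without wild-type intact 1 and 2 and wild-type castrated 1), 11 to 103 (14 without PTEN castrated 3) and 1 to 5 (3 and 2 without PTEN castrated 2 and 4EBP1 2). Classes of cells ranged over 0 to 4 for intact PTEN and 0 to 3 between the castrated groups. Pten gave -0.39 and -0.33 without wild-type intact 2 and 3, neither passing.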

Other observations

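In luminal cells of castrated against intact PTEN mice Reg3b fell by 6.23 (SE 0.72, edgeR adjusted p = 0.00315), while its relative Reg3g did not pass (1358 ± 299 CPM in intact and 2992 ± 970 CPM in castrated mice; edgeR adjusted p = 0.318). Both encode secreted antibacterial lectins. In fibroblasts Col10a1 had 1.28 ± 2.21 CPM in the intact wild type, 76.0 ± 20.4 CPM in intact PTEN, 115 ± 42.5 CPM in castrated PTEN and 0.972 ± 1.37 CPM in 4EBP1 libraries, the lowest mean of the PTEN groups. Sult1e1, which inactivates estrogen, fell in fibroblasts of castrated PTEN mice from 428 ± 152 to 6.11 ± 3.34 CPM.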
